A study of Homo sapiens with 6 samples.

How the data were processed

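The data were 6 messenger RNA libraries of SNU-668 cells, 3 with titles naming SPIN1 and 3 with titles naming NC. Per the labels' protocols, RNA was extracted with Trizol, enriched for poly(A) transcripts with oligo-dT, made into strand-specific libraries with the KAPA stranded kit by the dUTP method, and sequenced as paired ends on a NovaSeq instrument. FastQC, cutadapt, HISAT2 and StringTie and the genome build hg19 are named per the submitters' processing notes, with no versions or settings. The values were deposited by the authors as FPKM per gene, per the file headers. An FPKM value divides the fragments of a gene by its length and by the mapped fragments of the library, so a rise in a few very abundant genes lowers all others, and genes share reads with near-identical copies in a way that is not given in the sources used here. The deposited table held 11314 genes, all protein-coding, and for each gene the higher of the 2 group means was at least 0.5003 FPKM, a filter seen in the values and stated by no header. Noncoding genes, and genes below that level in both groups, were therefore not analysed here. There were 6 symbols listed more than once, and rows were told apart by gene identifier. Coordinates are those of the deposited table, on hg19.

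The low values were searched for steps of whole reads. In the 6 pairs of libraries of one group, 12 to 35 genes were under 0.15 FPKM in both, and at most 4 of their log2 ratios fell within 0.02 of each other, so no step was found and the depth of each library is unknown. No confidence interval or detection floor that needs the depth was computed, and the precision of each value is given by the spread between the 3 libraries of its group.

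Groups and replicate numbers came from the titles, because the genotype entries contradict them. Differences are coded as titled SPIN1 minus titled NC. Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, which left out 253 and kept 11061. On log2(FPKM + 1), limma 3.58.1 in R 4.3.3 was fitted with a mean-variance trend and robust moderation (statmod 1.5.0), and p-values were Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. A fold of group means is a ratio of mean FPKM, whereas a log2 difference is on the log2(FPKM + 1) scale. The levels of SPIN1 and ALKBH3 were also compared with a two-sided exact permutation test over all divisions of the 6 libraries into 3 and 3.

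The test, the samples, the lists and the rule for named genes were fixed before the data were examined. The rule named SPIN1, ALKBH3 and 10 ferroptosis genes, then the 8 largest increases and the 8 largest decreases among genes past the threshold with a mean of at least 2 FPKM and groups that did not overlap, then up to 4 members with the smallest adjusted p in each list, or 2 members where none passed. Genes named to complete a count of 5 or fewer were chosen after their values were seen. Some genes that the rule names are not reported here. The 32 lists cover ferroptosis, iron, redox and lipid metabolism, stress responses, growth, the cell cycle, inflammation, lineage and other cell types, and the protein families of SPIN1 and ALKBH3. Members were counted as higher, lower or not past the threshold over all genes and adjusted over the list alone. Lists with at least 5 tested members, 27 in all, were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, and with fry, each adjusted over the lists. A further 5 lists were chosen after the data were seen and adjusted among themselves. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

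The code was tested on simulated data with the real genes' means and spread. Among 11020 simulated genes, limma recovered 14.7% of 68 genes changed by 0.5 on the log2 scale, 62.1% of 66 changed by 1 and 92.4% of 66 changed by 2, with 12 false calls among 124. The data gave 3053 calls, and the adjustment is less strict where more genes are called, so these shares need not hold there. On 11021 simulated genes camera called a list of 40 genes shifted by 0.5 and 0 of 20 unshifted lists. The simulated genes varied independently of each other, so this says nothing about false calls for lists of correlated genes. Alternatives were a pseudocount of 0.1 or 0.01, no filter or a mean of at least 2 FPKM, median scaling, quantile normalization, no trend and no robust moderation, weights per library, the replicate number as a block, a log2 difference of at least 1 as well, and leaving out each library in turn. Leaving out both libraries numbered 1 was added after the data were seen.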

Results

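Messenger RNA was measured in 6 libraries from SNU-668, an established human gastric cancer cell line, here a subline described as resistant to erastin. Erastin blocks the cystine and glutamate exchanger of the plasma membrane and sets off ferroptosis, an iron-dependent cell death driven by lipid peroxidation. The titles name 3 libraries for SPIN1 and 3 for NC, and the treatment text speaks of a short hairpin RNA against SPIN1 or a control hairpin. The deposited table held 11314 protein-coding genes as FPKM (fragments per kilobase of gene model, scaled to the mapped fragments of the library). Median FPKM ran from 4.91 to 5.49 over the libraries, and 24 to 33 genes per library were listed at 0. The 13 mitochondrially encoded genes took 32.2% to 38.4% of the summed FPKM of a library. No counts came with the values, so the depth behind each value is unknown and no counting interval is given. Across genes, which are not independent replicates, the correlation of log2 values was 0.972 to 0.976 between libraries titled NC, 0.962 to 0.976 between libraries titled SPIN1 and 0.917 to 0.941 between the groups.

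The question posed by the titles was how transcripts differ between erastin-resistant cells with a hairpin against SPIN1 and cells with a control hairpin. The labels contradict each other on the groups: the genotype entries call the samples titled SPIN1 wild type and those titled NC the SPIN1 knockdown, and the design text names ALKBH3 in place of SPIN1. Every title also begins with RLS3, which no label explains, while the other texts speak of erastin. Groups were therefore taken from the titles, and "higher" and "lower" below mean higher or lower in the 3 libraries titled SPIN1 than in the 3 titled NC. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

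SPIN1, which encodes the histone reader spindlin 1 (ENSG00000106723.16_2, hg19 chromosome 9, 91003334 to 91093609, plus strand), was at 0.322, 6.18 and 7.97 FPKM in the libraries titled NC, replicates 1 to 3. In the libraries titled SPIN1 it was at 0.324, 0.629 and 2.49 FPKM. The group means were 4.82 ± 4.00 and 1.15 ± 1.17 FPKM (SD, n = 3 each), and the log2 difference of -1.17 (SE 0.77) did not pass limma's test (Benjamini-Hochberg adjusted p = 0.307). A two-sided exact permutation test gave p = 0.4, where the smallest p that 3 against 3 libraries allow is 0.1. The library titled NC replicate 1 lay at the level of the libraries titled SPIN1, and without it the log2 difference was -2.03 (SE 0.43, limma adjusted p = 0.0301). With a weight estimated for each library, the difference was -1.87 (limma adjusted p = 0.0248), and over all alternatives the adjusted p ran from 0.0248 to 0.601. Because the groups overlapped in SPIN1, its level did not check the labels, and each direction given below rests on the titles.

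ALKBH3, a demethylase of alkylated nucleic acids (ENSG00000166199.12_3, hg19 chromosome 11, 43902361 to 43941816, plus strand), was at 14.8, 10.9 and 10.8 FPKM in the libraries titled NC and at 7.40, 10.3 and 12.5 FPKM in those titled SPIN1. The groups overlapped, at 12.1 ± 2.27 and 10.1 ± 2.54 FPKM (SD, n = 3 each). The log2 difference of -0.26 (SE 0.20) did not pass limma's test (adjusted p = 0.381; exact permutation p = 0.4, two-sided), and it was 0.06 with both libraries numbered 1 left out, an alternative chosen after the data were seen.

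**Figure D1:**
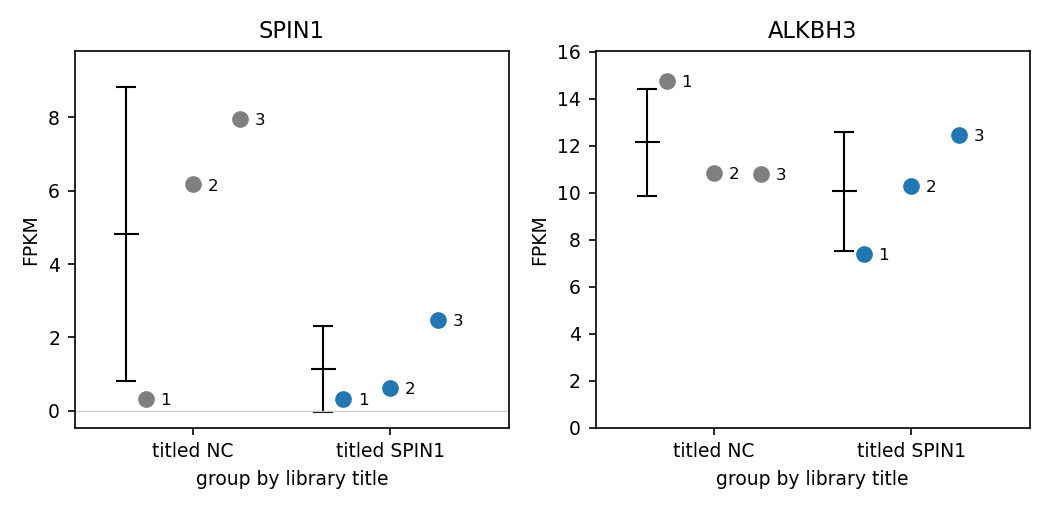
FPKM of SPIN1 (left) and ALKBH3 (right) in each library, grouped by title, with replicate numbers beside the points. Horizontal ticks and bars give the group mean and SD (n = 3). For SPIN1 the library titled NC replicate 1 sits at 0.322 FPKM, beside the libraries titled SPIN1, and for ALKBH3 the groups overlap.

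Genes of DNA replication were higher in the libraries titled SPIN1, and genes of the amino acid stress response driven by the transcription factor ATF4 were lower. GINS2, a subunit of the replicative helicase, stood at 23.9 ± 1.17 FPKM against 1.16 ± 0.109 (SD, n = 3 each), 20.5-fold higher. E2F1, the transcription factor that switches on S phase genes, was 7.79-fold higher at 65.0 ± 3.78 against 8.34 ± 0.195 FPKM. ASNS, which makes asparagine and is a classic ATF4 target, was 10.4-fold lower at 2.14 ± 0.337 against 22.3 ± 1.5 FPKM. The transcript of ATF4 itself was lower, at 100.3 ± 7.86 against 352 ± 5.11 FPKM.

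Over the 11061 genes tested, limma called 1914 genes higher and 1139 lower at a Benjamini-Hochberg adjusted p under 0.05. Of these, 430 were higher and 216 lower by at least 1 on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The 3 libraries of one title lay on one side of the 3 of the other for 3011 genes higher and 2074 lower, together 46.0% of those tested, where chance gives 10%. Of all calls, 62.7% were higher. After quantile normalization the split was 1596 higher and 1570 lower, or 50.4% higher, so the excess of higher calls depends on the scaling. Leaving out 1 library lowered the counts most without titled NC replicate 2 (1128 higher and 641 lower), titled NC replicate 3 (1270 and 679) and titled SPIN1 replicate 2 (1265 and 736), whereas weights per library raised them to 3106 and 2304. All 161 named genes past the threshold had groups that did not overlap, which the rule required of the largest increases and decreases. Of the 161, 115 stayed past it in each of the 6 fits that left out 1 library. Genes were mostly named for a large difference or a small p, so these counts do not stand for all called genes. Calls lost in fits without 1 library are given with the gene.

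Ranked by the difference of log2(FPKM + 1) among genes with a mean of at least 2 FPKM, the 8 largest increases were those of GINS2, TK1, E2F1, CDC45, MYBL2, SPC25, MCM5 and RRM2. The fold of the mean FPKM gives another order, in which genes of lower level such as CBR3, an NRF2 target, stand above some of these (10.7-fold). TK1, the thymidine salvage kinase of S phase, was at 98.5 ± 11.1 FPKM against 10.6 ± 2.04 (log2 difference 3.11, SE 0.15, limma adjusted p = 0.000253). CDC45, part of the replicative helicase, was 9.50-fold higher and MYBL2, a cell cycle transcription factor, 6.55-fold higher. SPC25, a kinetochore protein, stood at 16.5 ± 7.04 against 1.66 ± 0.303 FPKM. The helicase subunit MCM5 was 7.54-fold higher and RRM2, a subunit of ribonucleotide reductase, 8.74-fold higher. The fold of RRM2 rests on a spread-out 1.56 ± 1.03 FPKM in the libraries titled NC, against 13.7 ± 4.29. Its log2 difference ran from 2.32 to 2.86 with 1 library left out. Among the 8 largest decreases, too, the fold would place others, such as LCN2 (6.63-fold lower), above some. ADM2, a vasoactive peptide of the calcitonin family, was 20.5-fold lower at 0.665 ± 0.241 against 13.7 ± 1.6 FPKM (log2 difference -3.14, SE 0.14, limma adjusted p = 0.000213), and ASNS was second in that ranking. DMBT1, a secreted scavenger receptor of mucosal epithelia, was 15.1-fold lower. CST7, a cysteine protease inhibitor, was 6.61-fold lower and CSF3R, the receptor of granulocyte colony-stimulating factor, 6.03-fold lower. TXNIP, an inhibitor of thioredoxin and of glucose uptake, was at 1.58 ± 0.406 against 17.8 ± 6.32 FPKM, and DUSP5, a nuclear phosphatase of ERK, at 15.4 ± 2.54 against 85.2 ± 2.63 FPKM. BTG2, an antiproliferative p53 target, was at 11.9 ± 13.4 against 52.8 ± 1.14 FPKM (log2 difference -2.56, SE 0.65, limma adjusted p = 0.0302). In titled SPIN1 replicates 1 to 3 it was at 27.4, 4.33 and 4.03 FPKM, and its difference ran from -3.38 to -2.13 with 1 library left out. Its call was lost in 5 of the 6 fits without 1 library, the exception being the fit without titled SPIN1 replicate 1 (adjusted p up to 0.0893).

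Gene lists fixed before the data were examined were then counted. All 43 genes of the S phase and DNA replication list were higher, also when adjusted over the list alone, with a median log2 difference of 1.68. The origin recognition subunit ORC1 was at 8.06 ± 0.543 against 0.806 ± 0.00837 FPKM (SD, n = 3 each; limma adjusted p = 0.000202). Tested against the other genes with camera at a preset correlation of 0.01, the list had an adjusted p = 6.85e-27, and adjusted p = 0.0992 with an estimated correlation. Of 45 genes of G2 and mitosis, 29 were higher, 0 lower and 16 not past the threshold; adjusted over the list alone, 36 were higher. PTTG1, the securin that inhibits separase, was at 48.3 ± 7.93 against 21.6 ± 1.5 FPKM. MAD2L1, a spindle checkpoint protein, was at 6.19 ± 1.53 against 1.78 ± 0.192 FPKM, and the survivin gene BIRC5 at 8.38 ± 2.13 against 2.89 ± 0.433 FPKM. The camera call for this list (adjusted p = 5.89e-10) was lost with an estimated correlation (adjusted p = 0.514 with an estimated correlation). The library titled SPIN1 replicate 1 stood apart here: its mean deviation over the list was -0.01 on the log2 scale, against 0.71 and 0.94 for replicates 2 and 3, while the libraries titled NC lay at -0.65 to -0.45. Without it 42 of the 45 genes were higher, whereas 15 were higher without titled NC replicate 1, 17 without titled NC replicate 2 and 14 without titled SPIN1 replicate 2.

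The list of ATF4 targets of amino acid supply and the integrated stress response moved the other way. Of its 33 tested genes 28 were lower, 0 higher and 5 not past the threshold, and 30 were lower adjusted over the list alone. The median log2 difference was -1.15. AARS, the cytosolic alanyl-tRNA synthetase, was at 27.2 ± 1.68 against 68.0 ± 1.29 FPKM (SD, n = 3 each; limma adjusted p = 0.000504), and NUPR1, a stress-induced nuclear protein, at 0.912 ± 0.263 against 5.97 ± 0.358 FPKM (limma adjusted p = 0.000582). The camera call (adjusted p = 2.04e-17) held with an estimated correlation (adjusted p = 0.0145 with an estimated correlation). Among the 27 lists with at least 5 tested members, camera called 14 and this was the only one of them whose call held in that test. By fry, which asks whether the genes of a list move one way on balance and compares them with no other genes, 16 lists were called.

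**Figure D2:**
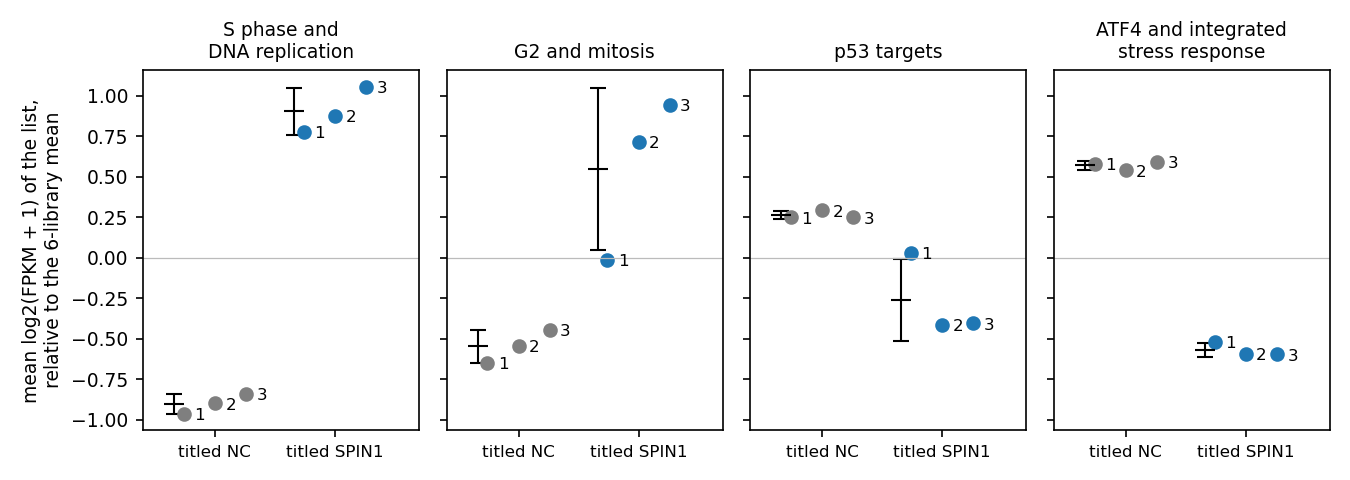
Mean deviation of log2(FPKM + 1) from the 6-library mean over the genes of 4 lists, in each library by title, with replicate numbers beside the points and horizontal ticks and bars for the group mean and SD (n = 3). The groups lie apart on the replication and ATF4 lists, whereas titled SPIN1 replicate 1 lies at -0.01 on the G2 and mitosis list and at 0.03 on the p53 list, away from the other 2 libraries of its group.

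Among genes tied to ferroptosis, SLC3A2 was lower and TFRC higher, whereas SLC7A11 and GPX4 did not pass the test. SLC7A11, the cystine-importing subunit of the exchanger that erastin blocks, was at 20.4 ± 2.29 against 22.2 ± 1.42 FPKM (SD, n = 3 each; log2 difference -0.12, limma adjusted p = 0.450). With weights per library it was past the threshold (log2 difference -0.23, limma adjusted p = 0.0409). Its partner SLC3A2, which is also on the ATF4 list, was lower, at 66.3 ± 3.92 against 110 ± 10.1 FPKM (log2 difference -0.73, limma adjusted p = 0.00317). GPX4, the peroxidase that reduces lipid hydroperoxides, was at 105 ± 8.55 against 107 ± 13.4 FPKM (log2 difference -0.03, limma adjusted p = 0.884). ACSL4, which loads polyunsaturated fatty acids into phospholipids, was at 30.3 ± 4.49 against 40.2 ± 3.64 FPKM (limma adjusted p = 0.0634), and the ubiquinone reductase gene AIFM2 at 14.9 ± 2.09 against 19.6 ± 0.818 FPKM (limma adjusted p = 0.0550). Both missed the threshold narrowly: ACSL4 was past it without titled SPIN1 replicate 2 (adjusted p = 0.0463) and AIFM2 without titled SPIN1 replicate 1 (adjusted p = 0.0235). In the other fits without 1 library neither gene passed, with limma adjusted p up to 0.177 for ACSL4 and 0.161 for AIFM2. Both were past it after median scaling (adjusted p = 0.0407 and 0.0364), quantile normalization (0.0478 and 0.0313) and with weights per library (0.0333 and 0.00200). With both libraries numbered 1 left out, an alternative chosen after the data were seen, AIFM2 was past it too (adjusted p = 0.0362). TFRC, the transferrin receptor, was higher at 39.0 ± 3.68 against 21.9 ± 1.12 FPKM (limma adjusted p = 0.00247). DHODH, which reduces ubiquinone in mitochondria, differed by -0.10 on the log2 scale (limma adjusted p = 0.579) and GCLM of glutathione synthesis by 0.08 (adjusted p = 0.713). The ferritin heavy chain FTH1 differed by 0.34 (limma adjusted p = 0.290) and the heme oxygenase HMOX1 by 0.76 (adjusted p = 0.133). None of these 4 was past the threshold. HMOX1 was at 38.6 FPKM in titled SPIN1 replicate 1 against 15.1 and 20.9 in replicates 2 and 3, and its difference was 0.40 without replicate 1, 1.05 without replicate 2 and 0.24 with weights per library. That of FTH1 ran from 0.17 without titled SPIN1 replicate 3 to 0.54 without titled NC replicate 2. The signs of GPX4 and GCLM turned without titled NC replicate 1 (0.07 and -0.02) and without titled SPIN1 replicate 3 (0.04 and -0.04). Those of GPX4, GCLM, DHODH and FTH1 turned with weights per library, and FTH1 passed the threshold after quantile normalization (adjusted p = 0.0322).

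Of 33 genes of ferroptosis defence, 6 were higher, 4 lower and 23 not past the threshold, and adjusted over the list alone 7 were higher and 6 lower. The glutathione reductase GSR was at 19.8 ± 2.68 against 8.79 ± 0.297 FPKM (SD, n = 3 each; limma adjusted p = 0.00141). The 4 lower genes were SLC3A2, the desaturase SCD, and SEPHS2 and SECISBP2 of selenoprotein synthesis, the last named losing its call in 4 of the 6 fits without 1 library (adjusted p up to 0.0723). The list median was -0.03 and its mean 0.07, and camera made no call (adjusted p = 0.726, direction down). Of 26 genes that promote ferroptosis, 6 were higher, 3 lower and 17 not past the threshold (6 and 5 adjusted over the list alone). Camera again made no call (adjusted p = 0.726), although fry called a shift upward on balance (adjusted p = 0.00696). The list median was 0.097 and its mean 0.043, where the median of all tested genes was 0.049. In mean deviation over the list the groups overlapped, titled SPIN1 replicate 2 (-0.030) lying under titled NC replicates 2 and 3 (-0.007 and -0.021). VDAC3, a channel of the outer mitochondrial membrane, was higher at 29.7 ± 1.36 against 16.2 ± 0.725 FPKM, and the lower genes were CHAC1, SAT1 and CARS. The 6 higher genes became 3 without titled NC replicate 2 and 3 without titled SPIN1 replicate 2, and 10 with weights per library. The 3 lower genes became 5 without titled SPIN1 replicate 2, after median scaling or after quantile normalization, and 6 with weights per library. Among 25 genes of iron handling 6 were higher, 5 lower and 14 not past the threshold (6 and 6 adjusted over the list alone; camera adjusted p = 0.803), while fry called a shift upward (adjusted p = 0.0411). The iron list had a median of 0.068 and a mean of 0.016. On it titled SPIN1 replicate 3 had the lowest mean deviation of the 6 libraries (-0.057). LCN2, the siderophore-binding lipocalin, was lower at 0.902 ± 0.297 against 5.98 ± 0.190 FPKM, and the other lower genes were STEAP4, PCBP2, SLC25A37 and FBXL5. SLC25A37 lost its call without titled NC replicate 3 (adjusted p = 0.0560) and FBXL5 in 5 of the 6 fits (adjusted p up to 0.146).

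NRF2 targets, which serve antioxidant and detoxifying reactions, were higher in 17 of 33 cases, with 0 lower and 16 not past the threshold (18 higher and 1 lower adjusted over the list alone). The quinone reductase NQO1 was at 165 ± 21.9 against 80.3 ± 3.10 FPKM (SD, n = 3 each; limma adjusted p = 0.00166). The peroxiredoxin PRDX1 was at 270 ± 16.8 against 154 ± 9.63 FPKM and the aldose reductase AKR1B1 at 515 ± 28.3 against 248 ± 13.6 FPKM. The camera adjusted p of 0.000635 was lost with an estimated correlation (adjusted p = 0.429 with an estimated correlation). In cholesterol synthesis 17 of 25 genes were higher, 0 lower and 8 not past the threshold (18 adjusted over the list alone). ACAT2, which condenses acetyl-CoA at the start of the pathway, was at 17.5 ± 2.13 against 4.31 ± 0.780 FPKM and SQLE, the squalene epoxidase, at 40.7 ± 1.96 against 23.2 ± 2.44 FPKM. This list had a camera adjusted p = 2.11e-05, and adjusted p = 0.0988 with an estimated correlation; 10 of its genes were higher without titled NC replicate 2 and 11 without titled SPIN1 replicate 3. Fatty acid synthesis and desaturation genes went both ways, 6 of 21 being higher, 2 lower and 13 not past the threshold (6 and 4 adjusted over the list alone; camera adjusted p = 0.940). ACLY, the source of cytosolic acetyl-CoA, was higher at 41.1 ± 7.07 against 22.5 ± 1.55 FPKM, whereas SCD was lower at 56.7 ± 5.12 against 101 ± 11 FPKM. SREBF1 was lower too, but its call was lost without titled NC replicates 1 and 3 (adjusted p = 0.0613 and 0.0555). The 6 higher genes became 2 without titled NC replicate 2 or titled SPIN1 replicate 2, and the 2 lower genes became 6 without titled SPIN1 replicate 1 and 5 without titled SPIN1 replicate 2.

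Energy metabolism genes were higher in part. Of 24 glycolysis genes 15 were higher, 0 lower and 9 not past the threshold, with 15 also adjusted over the list alone. PFKP, a phosphofructokinase, was at 35.5 ± 2.08 against 7.95 ± 0.386 FPKM (SD, n = 3 each; limma adjusted p = 0.000202), and the hexokinase HK1 at 52.2 ± 2.65 against 26 ± 1.49 FPKM. Camera gave the list an adjusted p = 2.41e-06, and adjusted p = 0.122 with an estimated correlation. The hypoxia response list, which shares 5 genes with glycolysis, had 12 of 27 genes higher, 2 lower and 13 not past the threshold, the same counts adjusted over the list alone (camera adjusted p = 0.00207; adjusted p = 0.141 with an estimated correlation). STC1, a secreted stanniocalcin, was at 11.3 ± 1.12 against 2.97 ± 0.223 FPKM, and BNIP3, a mitophagy receptor, at 12.7 ± 1.99 against 4.61 ± 0.167 FPKM. The 2 lower genes were VEGFA, which is also on the ATF4 list, and DDIT4, which lost its call in each of the 6 fits without 1 library (adjusted p up to 0.107). Of 46 nuclear-encoded genes of oxidative phosphorylation 25 were higher, 0 lower and 21 not past the threshold (29 adjusted over the list alone). ATP5C1 of the ATP synthase was at 96.7 ± 4.88 against 53 ± 0.779 FPKM and COX6C of cytochrome c oxidase at 31.8 ± 1.94 against 17.1 ± 0.380 FPKM. The camera call for this list (adjusted p = 8.10e-08) was lost with an estimated correlation (adjusted p = 0.0992 with an estimated correlation). Its 25 higher genes became 14 without titled NC replicate 2, titled NC replicate 3 or titled SPIN1 replicate 2, and 16 without titled SPIN1 replicate 3. Of the 13 mitochondrially encoded genes 3 were lower, namely MT-CYB, MT-ND1 and MT-ND2, and 10 not past the threshold, with 3 lower adjusted over the list alone (camera adjusted p = 0.0875). After quantile normalization 3 genes of this list were higher, and MT-ND2 lost its call in 5 of the 6 fits without 1 library (adjusted p up to 0.0969).

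Immediate early genes were lower in 16 of 25 cases, with 0 higher and 9 not past the threshold (17 lower adjusted over the list alone; median log2 difference -0.65). EGR1, an early growth response factor, was at 9.18 ± 2.01 against 32.4 ± 2.51 FPKM (SD, n = 3 each; limma adjusted p = 0.000997), and the nuclear receptor NR4A1 at 0.667 ± 0.182 against 2.69 ± 0.442 FPKM. The list had a camera adjusted p = 2.54e-09, and adjusted p = 0.0992 with an estimated correlation, and 10 genes were lower without titled NC replicate 2. FOXO and PI3K-AKT target genes were lower in 9 of 21 cases, higher in 1 and not past the threshold in 11, with the same counts adjusted over the list alone (camera adjusted p = 0.000202; adjusted p = 0.0992 with an estimated correlation). The insulin receptor gene INSR was at 0.324 ± 0.0111 against 1.48 ± 0.0672 FPKM and the transcriptional coregulator CITED2 at 7.57 ± 0.266 against 15.9 ± 0.942 FPKM. The 1 higher gene was PDK4, a kinase that holds back pyruvate dehydrogenase, whose call was lost in 5 of the 6 fits without 1 library (adjusted p up to 0.104). Of 29 p53 targets 11 were lower, 4 higher and 14 not past the threshold (14 and 5 adjusted over the list alone). TNFRSF10B, a death receptor, was at 17.6 ± 2.43 against 32.1 ± 0.930 FPKM and SESN2, a sestrin that is also on the ATF4 list, at 4.58 ± 3.16 against 22.1 ± 0.909 FPKM. The higher genes were FDXR, DDB2, BAX and POLH, of which DDB2, BAX and POLH lost their calls in 5, 4 and 6 of the 6 fits (adjusted p up to 0.0881, 0.124 and 0.136). The p53 list had a camera adjusted p = 0.00630, and adjusted p = 0.332 with an estimated correlation. Its mean deviation was 0.03 in titled SPIN1 replicate 1 against -0.41 and -0.41 in replicates 2 and 3. Without that library 14 genes were lower, and the 11 became 6 without titled NC replicate 1 or 2, 5 without titled NC replicate 3 or titled SPIN1 replicate 2 and 4 without titled SPIN1 replicate 3.

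**Figure D3:**
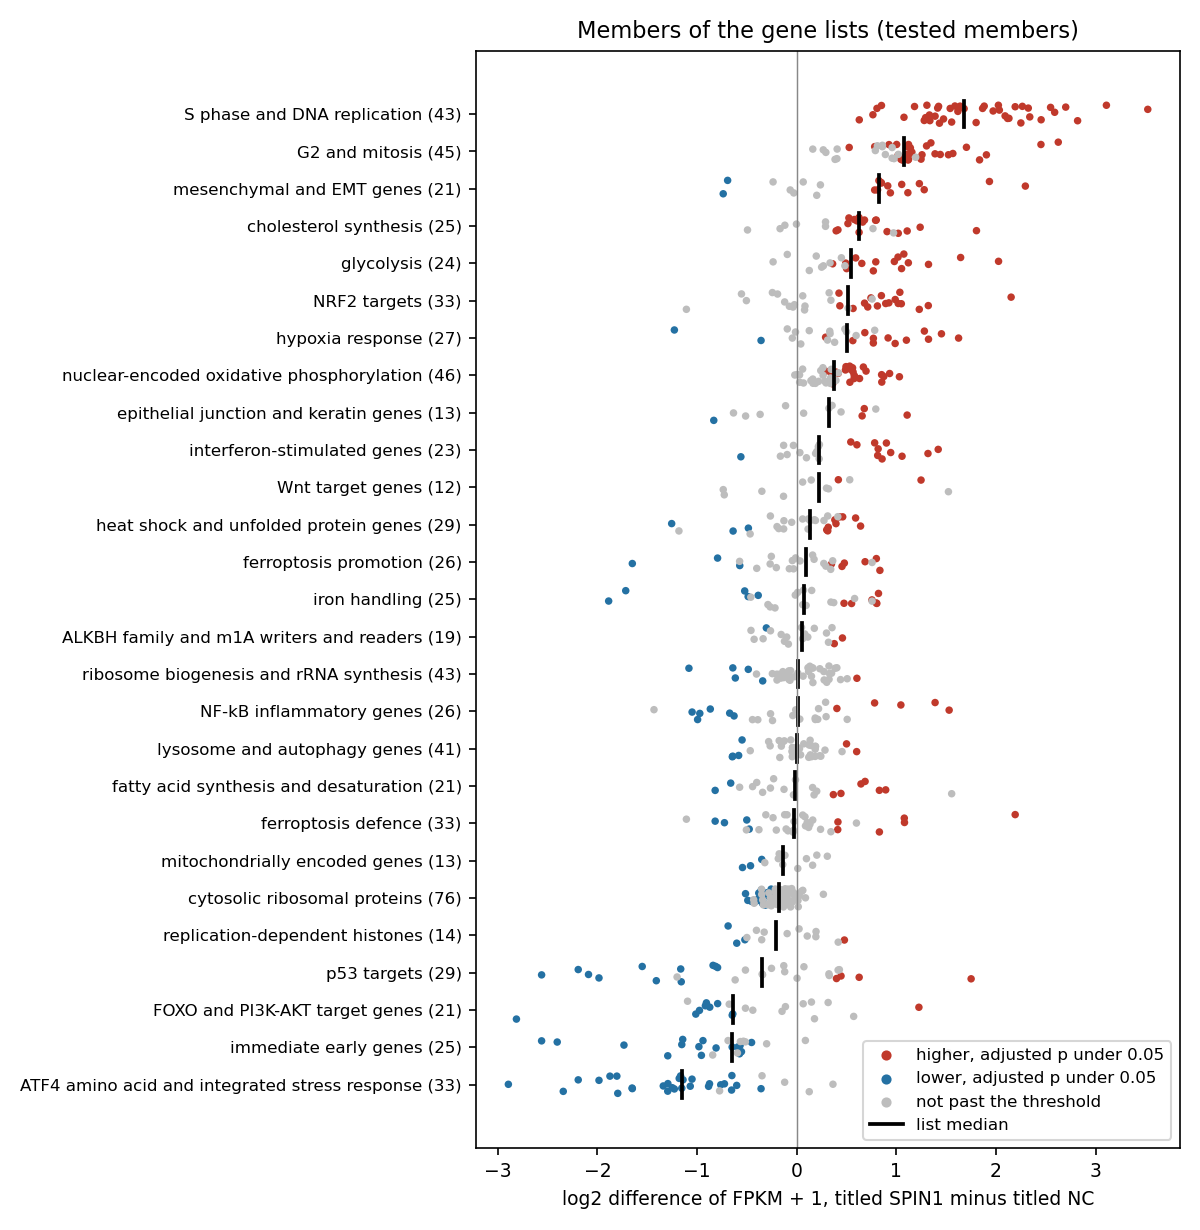
Log2 difference of FPKM + 1, titled SPIN1 minus titled NC, of each tested member of the 27 lists with at least 5 tested members, ordered by the list median (black tick), with the number of members in parentheses. Red points were higher and blue points lower at an adjusted p under 0.05 by limma, grey points were not past it, and the medians run from 1.68 for S phase and DNA replication to -1.15 for the ATF4 list.

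Interferon-stimulated genes were higher in 11 of 23 cases, lower in 1 and not past the threshold in 11, with the same counts adjusted over the list alone (camera adjusted p = 0.00356; adjusted p = 0.0992 with an estimated correlation). ISG15, a ubiquitin-like modifier, was at 12.6 ± 1.04 against 4.17 ± 1.12 FPKM (SD, n = 3 each; limma adjusted p = 0.00256). STAT2, a transcription factor of interferon signalling, was the 1 lower gene, and its call was lost in 5 of the 6 fits without 1 library (adjusted p up to 0.133). NF-kB inflammatory genes were split: 5 of 26 were higher, 6 lower and 15 not past the threshold (5 and 7 adjusted over the list alone; camera adjusted p = 0.680). The higher genes were IL32, CXCL1, CCL5, BIRC3 and IRAK2, the last 2 losing their calls in 4 and 6 of the 6 fits (adjusted p up to 0.0983 and 0.120). IL6 was lower at 57.4 ± 7.93 against 115 ± 8.79 FPKM, and the chemokine CCL20 at 0.746 ± 0.0377 against 2.63 ± 0.372 FPKM. Without titled NC replicate 1, titled NC replicate 2 or titled SPIN1 replicate 1 there were 3 higher genes, and without titled NC replicate 3 there were 3 lower ones.

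Mesenchymal and EMT genes were higher in 13 of 21 cases, lower in 2 and not past the threshold in 6 (14 and 2 adjusted over the list alone; median log2 difference 0.83). The matrix protein fibronectin, from FN1, was at 65.5 ± 10.8 against 12.4 ± 0.757 FPKM (SD, n = 3 each; limma adjusted p = 0.000463). The intermediate filament gene VIM was at 133 ± 8.61 against 73.5 ± 3.39 FPKM. TGFBI and CYR61, both matrix-associated proteins, were lower; TGFBI lost its call without titled NC replicate 3 (adjusted p = 0.0507) and CYR61 in 4 of the 6 fits (adjusted p up to 0.0908). Camera gave an adjusted p = 0.000810, and adjusted p = 0.141 with an estimated correlation. Of 13 epithelial junction and keratin genes 3 were higher, 1 lower and 9 not past the threshold (3 and 2 adjusted over the list alone; camera adjusted p = 0.718). KRT8, DSG2 and KRT18 were higher and TJP3 lower. KRT8 lost its call without titled NC replicate 3 (adjusted p = 0.0509), DSG2 in 3 and KRT18 in 5 of the 6 fits (adjusted p up to 0.0613 and 0.118).

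Cytosolic ribosomal protein genes were lower in 16 of 76 cases, with 0 higher and 60 not past the threshold, and in 9 cases adjusted over the list alone. RPL10 was at 203 ± 9.06 against 291 ± 19.8 FPKM (SD, n = 3 each; limma adjusted p = 0.00541) and RPS27 at 544 ± 9.73 against 715 ± 26.6 FPKM; many processed copies of these genes exist, and how the deposited values split shared reads is not known. The camera adjusted p of 3.10e-08 became adjusted p = 0.429 with an estimated correlation. The 16 lower genes became 28 without titled SPIN1 replicate 1, 6 without titled NC replicate 1 or 3, 5 without titled SPIN1 replicate 3 and 4 without titled NC replicate 2 or titled SPIN1 replicate 2, and 46 with weights per library. Of 43 genes of ribosome biogenesis 1 was higher, NOP56, and 5 were lower, NOP2, TAF1D, UTP14A, RRP12 and PES1, with 37 not past the threshold (1 and 4 adjusted over the list alone; camera adjusted p = 0.680). TAF1D and UTP14A lost their calls in 3 of the 6 fits (adjusted p up to 0.0682 and 0.0600), RRP12 in 4 and PES1 in 5 (up to 0.0655 and 0.129). Heat shock and unfolded protein genes were higher in 9 of 29 cases, lower in 3 and not past the threshold in 17 (10 and 5 adjusted over the list alone; camera adjusted p = 0.695). The mitochondrial chaperonin genes HSPE1 and HSPD1 were higher, the latter losing its call without titled SPIN1 replicate 3 (adjusted p = 0.0505). DNAJB9, HERPUD1 and SEL1L of the endoplasmic reticulum were lower, the last 2 losing their calls in 5 and 4 of the 6 fits (adjusted p up to 0.0947 and 0.131). The 9 higher genes became 4 without titled NC replicate 1 or titled SPIN1 replicate 2, 3 without titled NC replicate 3 and 2 without titled NC replicate 2 or titled SPIN1 replicate 3, and 3 after median scaling. Among 41 lysosome and autophagy genes, OPTN and ATP6V1A were higher, MAP1LC3B, WIPI1, TFEB and GABARAPL1 lower and 35 not past the threshold (1 and 3 adjusted over the list alone; camera adjusted p = 0.679). OPTN lost its call without titled NC replicates 1 and 2 (adjusted p = 0.0529 and 0.0700), and ATP6V1A and GABARAPL1 in 5 of the 6 fits (adjusted p up to 0.0915 and 0.139).

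The remaining lists were small or little changed. Of 14 replication-dependent histone genes, whose transcripts mostly lack the poly(A) tail that the oligo-dT selection needs, 1 was higher, HIST1H1C, and 3 were lower, HIST1H2AC, HIST2H4A and HIST1H2BD, with 10 not past the threshold (1 and 3 adjusted over the list alone; camera adjusted p = 0.302). Each of these 4 lost its call in 2 to 5 of the 6 fits without 1 library (adjusted p up to 0.0907). Of 12 Wnt target genes BIRC5 and CCND1 were higher, 0 lower and 10 not past the threshold (1 adjusted over the list alone; camera adjusted p = 0.679), CCND1 losing its call in 5 of the 6 fits (adjusted p up to 0.104). In the spindlin family and its partners, SPIN2B and C11orf84, the gene of a spindlin-binding protein, were higher (2 adjusted over the list alone), and SPIN1 was the remaining tested gene. Both lost their calls in 4 of the 6 fits (adjusted p up to 0.134 and 0.0849). SPIN2B has a near-identical copy, so its value is uncertain. Of 19 genes of the ALKBH family and of writers and readers of methyladenosine, ALKBH4 and TRMT10C were higher, YTHDF1 lower and 16 not past the threshold (0 and 0 adjusted over the list alone by limma; camera adjusted p = 0.726). ALKBH4 lost its call in 5 and the others in 6 of the 6 fits (adjusted p up to 0.168).

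Markers of other cell types were mostly not in the deposited table. Of 24 leukocyte genes 3 could be tested, of which LYZ and CD14 were lower (2 adjusted over the list alone) and 1 was not past the threshold; CD14 stood at 11.5 ± 3.39 against 24.1 ± 0.760 FPKM (SD, n = 3 each; limma adjusted p = 0.0116). Of 16 endothelial genes 3 were tested and 0 passed limma's threshold, over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. The endothelial cadherin CDH5 was at 0.844 ± 0.447 against 1.54 ± 0.170 FPKM (limma adjusted p = 0.101). It was past the threshold without titled SPIN1 replicate 1 (adjusted p = 0.0467). EGFL7 was at 49.7 ± 9.87 against 51.8 ± 11.3 FPKM (limma adjusted p = 0.860), and its sign turned without titled NC replicate 1 (0.11) and titled SPIN1 replicate 3 (0.09). Of 16 erythroid genes 3 were tested and 0 passed limma's threshold, also adjusted over the list alone, with 0 at an unadjusted p under 0.05. HBA1 was at 5.30 ± 0.971 against 4.43 ± 0.799 FPKM (limma adjusted p = 0.362) and EPOR at 1.17 ± 0.309 against 0.910 ± 0.223 FPKM (adjusted p = 0.389). Of 35 gastric and intestinal lineage genes 4 were tested; KLF5, an epithelial transcription factor, was lower at 25.7 ± 5.55 against 38.4 ± 3.84 FPKM (limma adjusted p = 0.0479), 3 genes were not past the threshold and 0 were past it adjusted over the list alone. KLF5 lost its call in 4 of the 6 fits without 1 library (adjusted p up to 0.137).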

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

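All alternatives here were planned except the one that left out both libraries numbered 1, which was chosen after the data were seen. The counts of 1914 genes higher and 1139 lower stayed within 1.5 times under other pseudocounts, filters and scalings. They were 3106 and 2304 with weights per library, and 430 and 216 when a log2 difference of at least 1 was also asked for, which is stricter by construction. Leaving out 1 library gave 1128 to 2045 higher and 641 to 1251 lower; fewer libraries were then tested, and why single libraries mattered more was not tested. SPIN1 passed the threshold with weights per library (-1.87, adjusted p = 0.0248) and ranged from -2.03 to -0.65 with 1 library left out, while its adjusted p ran from 0.0248 to 0.601 over all alternatives; the weights count libraries that stand apart for less. ALKBH3 was 0.059 with both libraries numbered 1 left out. With weights per library the signs turned for GPX4 (0.079), DHODH (0.035), GCLM (-0.062), FTH1 (-0.031) and EGFL7 (0.059), and GPX4 was 0.043 with both libraries numbered 1 left out. With 1 library left out, GPX4 ranged from -0.096 to 0.072, GCLM from -0.039 to 0.15 and EGFL7 from -0.19 to 0.11. The cause was not tested. Of the other values of named genes, 2487 kept direction and side of the threshold, 235 lost their call and 16 gained one. At the preset correlation, the 14 lists called by camera kept direction and call in 224 of 224 combinations of list and setting, whereas with an estimated correlation 1 of the 14 kept its call. The estimates ran from -0.0273 to 0.819 over the 14. Those for cholesterol synthesis (-0.0273) and interferon-stimulated genes (-0.0148) lay under the preset 0.01. A higher correlation was therefore not what cost these lists their calls. The estimate for the ATF4 list (-0.0233) lay under the preset too, yet its camera adjusted p rose from 2.04e-17 to 0.0145. The second camera test thus gave larger p-values even without a higher correlation, so a call lost in it need not reflect correlated genes. Whether the replicate numbers pair the samples stays open, as no label says so. Deviations of same-numbered libraries correlated across genes at 0.216, 0.0551 and 0.148. Those of libraries with different numbers correlated at -0.211 to 0.0757, the highest being titled NC replicate 2 with titled SPIN1 replicate 3. With the number as a replicate block, 2048 genes were higher and 1251 lower, ACSL4 passed the threshold (adjusted p = 0.0289), the SPIN1 difference was -1.17 and that of ALKBH3 -0.26. The depth is unknown, so what it limits could not be computed.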

Other observations

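The synthetase, ERK feedback, proteasome and DNA repair lists were chosen after the data were seen, and so were the tests of labels, transcript models, SPIN1 level as a cause, growth state, scaling and chromosome blocks. The other splits, the tests on length and GC content, quantile normalization as a setting, the fits without 1 library and the SPIN1 difference were planned. Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs for translation, were lower in 11 of 20 cases, higher in 1 (RARS) and not past the threshold in 8. MARS was at 6.85 ± 0.268 against 23.5 ± 0.647 FPKM (SD, n = 3 each; limma adjusted p = 0.000258) and SARS at 45.6 ± 1.08 against 120 ± 2.96 FPKM. Of 17 mitochondrial synthetases YARS2 and LARS2 were higher and NARS2 lower, all 3 losing their calls in some of the 6 fits without 1 library (adjusted p up to 0.0639, 0.136 and 0.0803), and 14 were not past the threshold. The medians of both lists differed by -0.80 on the log2 scale, which is a description and not a test, since the lists were chosen for the pattern. AARS, GARS and WARS are also on the ATF4 list. The ERK feedback list holds feedback regulators and other genes that ERK signalling induces, such as CCND1. Its genes were lower in 7 of 15 cases, higher in 1 and not past the threshold in 7. DUSP5, which was lower, is on both this list and that of immediate early genes. The receptor inhibitor ERRFI1 was at 6.68 ± 0.821 against 31.8 ± 3.89 FPKM and the phosphatase DUSP4 at 70.2 ± 10.1 against 140 ± 1.44 FPKM. The 1 higher gene was CCND1, whose call was lost in 5 of the 6 fits (adjusted p up to 0.104).

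Proteasome subunits were higher in 22 of 31 cases, with 0 lower and 9 not past the threshold. PSMB3 was at 139 ± 2.94 against 65.9 ± 5.33 FPKM and PSMC3 at 69.1 ± 2.66 against 37.9 ± 5.19 FPKM (SD, n = 3 each; limma adjusted p = 0.000675 and 0.00293). Without titled NC replicate 1 there were 14. Genes of homologous recombination and the Fanconi anaemia pathway were higher in 20 of 28 cases and not past the threshold in 7. FANCI was at 12.6 ± 2.19 against 3.05 ± 0.410 FPKM and the nuclease gene EXO1 at 7.43 ± 1.52 against 1.13 ± 0.302 FPKM. RAD50 was lower, its call lost in 4 of the 6 fits (adjusted p up to 0.0652). The camera calls for the cytosolic synthetase, ERK feedback, proteasome and DNA repair lists (adjusted p = 3.45e-05, 0.000847, 2.70e-08 and 2.70e-08) were lost with an estimated correlation (adjusted p = 0.107 with an estimated correlation in each). For ERK feedback the estimate of -0.0326 lay under the preset 0.01, so a higher correlation did not cost it its call. The mitochondrial synthetase list was not called by camera (adjusted p = 0.167), while fry called a shift upward (adjusted p = 0.0367). All of these lists were chosen after the data were seen, so their camera and fry values are descriptions and not tests.

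Of the 10 splits of the 6 libraries into 3 and 3, 1, the split by title, gave 3053 genes past the threshold, and the highest of the others gave 1 gene. Camera at its preset correlation called 14 lists in the split by title, which made 1 of 10 splits with as many, and up to 13 in the others, each of which leaves 1 library of one title among 2 of the other. Splits of 3 against 3 are too few for a share under 0.05. Over 242 blocks of 10 Mb with at least 15 tested genes, the median log2 difference lay at most 0.313 from that of all genes. This was under the bound of 0.5 set for a gain or loss of 1 chromosome copy of 2. The log2(FPKM + 1) scale understates the change of genes with low FPKM, so a gain could also fall under this bound and is not excluded.

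SPIN1 was as low in the library titled NC replicate 1 as in the libraries titled SPIN1. A wrong label on that library is argued against by the other genes: over those called without it, its median position between the other libraries titled NC (0) and the mean of those titled SPIN1 (1) was 0.0569. The deposited SPIN1 value may depend on which transcript models were assembled, but no values of single transcripts were examined. Within the libraries titled NC, its highest to lowest ratio of 24.8 was matched by 0.585% of genes of similar level (16 of 2737). Of these 16, 3 had titled NC replicate 1 as the odd library, and a lowest value of 0 counted as a match. Such ratios do not show which models were assembled, so this stays open. Whether the genotype entries and not the titles name the knockdown stays open too, as the SPIN1 difference of -1.17 was lower in the libraries titled SPIN1 but did not pass the test. Knockdown by the hairpin, the biological explanation that the titles give, cannot be told apart from these without an independent measure of SPIN1.

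Replication genes were higher and ATF4 targets lower in the libraries titled SPIN1. Scaling and sequence bias are argued against as the whole cause, since the list medians were 1.62 and -1.21 after quantile normalization and 1.56 and -1.23 after a fit on transcript length, GC content and mean level, close to 1.68 and -1.15 before. The level of SPIN1 as deposited may not be what sets the replication genes, as titled NC replicate 1, low in SPIN1, lay at a median position of -0.0391 on that list, but this is 1 library. A difference in growth state or batch between the cultures of each group could also give both changes. Libraries titled SPIN1 that differed on the mitotic list by 0.957 differed by 0.0773 on the ATF4 list, where the slope between groups would give 0.996, yet with 3 libraries per group such a state cannot be told apart from the hairpin.

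The library titled SPIN1 replicate 1 lay apart from the other 2 of its group, by -0.842 on the G2 and mitosis list, by 0.439 on the p53 list and by 0.365 on the epithelial junction and keratin list. A wrong label is argued against, since over genes called without it its median position towards the libraries titled NC was 0.226 and the upper quartile 0.492, and so is scaling, since its distance on the mitotic list was -0.825 after quantile normalization. Still, that library lay nearer the other group in 24.4% of those genes, against 4.13% to 8.94% for the other libraries, each over its own genes. The position bears on a full swap of labels only. With the replication and ATF4 genes of that library near those of the other 2, no biological explanation was tested.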
